A study of Mus musculus with 5 samples.

How the data were processed

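Single nuclei of the hippocampus were captured with a 3′ kit (version 3.1) after sorting of Hoechst-positive nuclei, and for the transfer groups the nuclei of 3 mice were combined per group. The number of mice behind each library of the depletion experiment is not given in the sources used here. Each of the 5 groups is 1 library: transfer of vehicle-treated young, vehicle-treated aged and PTx-treated aged CD8+ T cells into B6.SJL mice, and isotype or CD8a antibody in aged C57BL/6 mice. The deposited matrices hold whole-number UMI counts per gene and nucleus, which the authors made with bcl2fastq and Cell Ranger on mm10. The submitters' processing notes name Cell Ranger 7.1 and Seurat, and the headers of the filtered matrices name version 7.0.1. Whether reads in introns were counted, and the annotation release, are not given in the sources used here. Filtered matrices of called barcodes were used for all 5 libraries. For the isotype and CD8a antibody libraries the deposited raw matrices, with the counts of all barcodes, were used for free RNA and for droplets without a called nucleus. For the transfer libraries the deposited aggregate matrix was used as an alternative: it holds the same barcodes with 75.5%, 48.3% and 100% of the UMIs of the young, aged and PTx libraries, and median UMIs of 3710, 3765 and 3603.

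The libraries (young, aged and PTx transfer, isotype, CD8a antibody) held 87208598, 107669039, 103099756, 76419333 and 86653305 UMIs. Nuclei with 500 or more genes and at most 5% mitochondrial UMIs numbered 15319, 11397, 24906, 12489 and 12497. Doublets were called per library with Scrublet in scanpy 1.11.5 with an expected rate of 0.8% per 1000 nuclei and the automatic threshold, which removed 8.00%, 5.98%, 12.3%, 4.70% and 5.99%. At this depth a gene of a class entered the comparison at 50 or more CPM (counts per 1000000 UMIs of the class) in 1 of the 2 libraries and 100 or more UMIs over both.

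All nuclei were clustered together. Counts were scaled to equal totals and logged, 2964 variable genes were kept (3000 requested within libraries, less sex-linked, mitochondrial, ribosomal and haemoglobin genes), and each library was centred and scaled on its own and clipped at 10. No other step aligned the libraries. Leiden clustering (resolution 1, 15 neighbours, 40 principal components) gave 39 clusters. Each was scored with 22 marker sets fixed before the data were examined, as were the gene lists, the size rule and the choice of named genes. A cluster took the name of its best set if the mean log2 ratio of the markers against all other nuclei was 0.6 or more, with a lead of 0.3 over the next set, 3 or more markers at 20 CPM, under 50% doublets, and no more markers of another set than of its own among its top 10 genes at 50 CPM. A cluster with low counts for its libraries and none of its own markers among its top 10 genes also stayed unnamed. These thresholds were chosen after the data were seen. At the alternative Leiden resolution of 2, the rule on low counts alone left out cluster 0, which scored best as oligodendrocyte. It had 1460, 1348 and 1572 kept nuclei in the transfer libraries (young, aged, PTx), and 78 with isotype and 124 with CD8a antibody. Named were 22 clusters, and the 17 unnamed ones held 15.2%, 16.3%, 19.8%, 16.7% and 14.3% of nuclei (order of libraries as above). Dentate granule, CA1, CA2/CA3 and GABAergic neurons, astrocytes, oligodendrocytes and microglia, fixed beforehand, were compared where they had 100 or more nuclei in each library. Oligodendrocyte precursors and subicular or cortical neurons were not among them.

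For each class, UMIs were summed over nuclei and expressed as CPM. With 1 library per group no test between groups was made and no p-value is given. A gene was past the size rule if its CPM differed by 1.5-fold or more. The 95% interval of a ratio is the conditional exact binomial interval for counting error only, and was not part of the rule. Intervals of CPM are exact Poisson and those of percentages exact binomial. Comparisons were aged against young donor cells, PTx against vehicle for aged donor cells, CD8a antibody against isotype, and PTx-treated aged against young donor cells. Of 30 gene lists, those with 5 or more members at 20 CPM in a class were summarised by their median log2 ratio, set beside the medians of 10000 random lists of genes matched on expression in 20 bins. This gave 292 medians, of which 87 lay in the outermost 2.5% on either side. Relations between comparisons are Pearson correlations of log2 ratios across genes. Where a library entered both, its nuclei were split at random into 2 parts. Gene coordinates and lengths came from GENCODE vM21 (GRCm38), in which 32235 of 32285 gene IDs were found (99.8%).

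Named genes were, per comparison and class, the 2 with the largest ratio each way, ranked by the bound of the interval nearest to no difference, among genes at 50 CPM and 100 UMIs whose class level was at least that of the whole library in the library where it was higher. Mitochondrially encoded, ribosomal protein, haemoglobin and sex-linked genes and unnamed gene models were left out. Up to 4 members of each list described were named by the same minimum, with Cd8a, Gzmk and the other T cell genes.

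The calls were tested on simulated Poisson counts with the depth and expression of each class, with 300 genes per fold and comparison. Changed genes and shifted lists were drawn only among genes with a mean of 2 times the 50 CPM minimum or more. Their shares were thus not measured for genes nearer to it. For aged against young, PTx against vehicle, CD8a antibody against isotype and PTx against young, 46 of 20076, 56 of 20309, 28 of 19119 and 35 of 19320 unchanged genes were called. Genes changed 1.5-fold were called in 51.7%, 49.7%, 48.0% and 51.0% of cases, and genes changed 2-fold in 300, 300, 300 and 299 of 300. The intervals held the true ratio for 95.1%, 95.2%, 95.2% and 95.2% of genes. Of 120 unchanged lists per comparison, 4, 9, 6 and 3 lay in the outermost 2.5% on either side, and all 6 shifted lists did.

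Alternatives were no doublet removal, a stricter filter (1000 genes, 1% mitochondrial), Leiden resolution 2, ratios centred on the median gene, equal weight per nucleus, nuclei thinned to 1000 UMIs with shallower nuclei left out, the aggregate matrix (transfer comparisons), subtraction of free RNA (depletion comparison), no CPM minimum with 20 UMIs, a 2-fold rule, all list members with a pseudocount of 1 or members at 50 CPM, and for relations the genes past 1.5-fold only. Free RNA was estimated from droplets with at most 100 UMIs, as the largest share that the least expressed foreign marker set allowed. Chosen after seeing the data were 2 more: subtraction of the median ratio of genes of like length (50 bins), and subtraction of the median ratio of the gene in the other classes where 3 or more held it. Software was python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9, with seed 1.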

Results

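Nuclei of the mouse hippocampus were sequenced from 5 groups of mice, 1 library per group, with a 3′ kit (version 3.1). In 3 groups, B6.SJL mice that had first been given an antibody against CD8a received CD8+ T cells by vein on days 0 and 11 and were killed on day 24. The donor cells came from young mice of 3–4 months or from aged mice of 22–28 months, and were incubated for 24 hours with vehicle or, for 1 part of the aged cells, with 0.5 μg/mL pertussis toxin (PTx). In the other 2 groups, aged C57BL/6 mice of 22–24 months received an antibody against CD8a or the IgG2b isotype control every 4 days. The libraries held 15527 nuclei after transfer of young cells, 11533 after transfer of aged cells, 25161 after transfer of PTx-treated aged cells, 16194 with isotype and 15237 with CD8a antibody. Median UMIs per nucleus were 4916, 7809, 3603, 2039 and 2557 in the same order, and median genes 2262, 3192, 1837, 1066.5 and 1261. Because each group is 1 library, no difference could be set against the spread between libraries, and each interval below is a 95% interval for counting error only. The experiments ask how aged CD8+ T cells act on the young hippocampus, whether their migration matters for this, and what the loss of peripheral CD8+ T cells does to the aged hippocampus.

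After filtering and removal of doublets, 14093, 10716, 21855, 11902 and 11748 nuclei were kept (young, aged and PTx transfer, isotype and CD8a antibody). Dentate granule neurons made up 22.8%, 18.6%, 16.7%, 14.1% and 14.9% of them, CA1 pyramidal neurons 13.9%, 12.9%, 11.8%, 8.44% and 9.15%, and CA2/CA3 pyramidal neurons 5.27%, 6.31%, 4.95%, 3.07% and 3.56%. GABAergic interneurons were 8.63%, 8.58%, 8.84%, 5.49% and 5.73%. Oligodendrocytes were 20.9%, 24.2% and 23.8% of nuclei in the transfer libraries against 37.7% and 36.4% in the aged mice. Microglia were 4.69%, 5.13% and 4.49% against 7.09% and 7.80%. The sort and the loading set these shares too, and the transfer and depletion experiments differed in strain, age and treatment. Of the classes chosen for comparison beforehand, these 6 had 100 or more nuclei in each library and were compared gene by gene, while astrocytes (96, 66, 116, 95 and 111 nuclei) had too few. Other classes, such as oligodendrocyte precursors, were not among those chosen.

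The first comparison set recipients of aged CD8+ T cells against recipients of young CD8+ T cells. Aged CD8+ T cells are richer in effector cells that release cytokines, granzymes and chemokines, and the comparison shows what the hippocampus of a young recipient holds after their transfer. The dentate gyrus relays cortical input to CA3 and CA1 and is where new granule neurons form. Microglia and oligodendrocytes carry receptors for T cell cytokines.

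Summed over the 6 classes, 2175 results of a gene in a class lay past the 1.5-fold rule, 912 higher and 1263 lower after aged cells. By class, 101 genes were higher and 158 lower in dentate granule neurons (3589 tested), 102 and 130 in CA1 (3524), 89 and 118 in CA2/CA3 (3292), 136 and 128 in GABAergic interneurons (3781), 217 and 376 in oligodendrocytes (3981) and 267 and 353 in microglia (4026). Many of the lower genes in neurons were of the kinds left out of naming, such as unnamed gene models. They were 99 in dentate granule, 94 in CA1, 81 in CA2/CA3 and 87 in GABAergic neurons, against 9, 6, 4 and 8 of the higher genes. Of the genes past the rule, 56 were higher and 65 lower in 4 or more classes. The genes higher in all 6 classes were Atp6v0b (a subunit of the vacuolar proton pump), Cox7c (cytochrome c oxidase), Dalrd3 and Ubb (ubiquitin), 4 in number and chosen for naming after their values were seen. The ratios followed gene length, with a Spearman correlation between −0.527 and −0.401 over the 6 classes, with higher ratios for shorter genes. The genes higher past the rule had median lengths of 7.80 to 12.8 kb. Those lower past it were long in oligodendrocytes and microglia (206 and 291 kb, against 62.4 and 58.2 kb for all tested genes), but in the 4 neuronal classes they were shorter (30.8 to 31.5 kb) than the tested genes (77.0 to 81.7 kb). With the length trend removed, 351 results were higher and 1248 lower, and of the 912 and 1263 found without removal 228 and 873 stayed (among the lower, 501 of 534 in neurons and 372 of 729 in oligodendrocytes and microglia). The correlation of the log2 ratios between pairs of classes had a median of 0.655 (0.500 to 0.934).

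**Figure D1:**
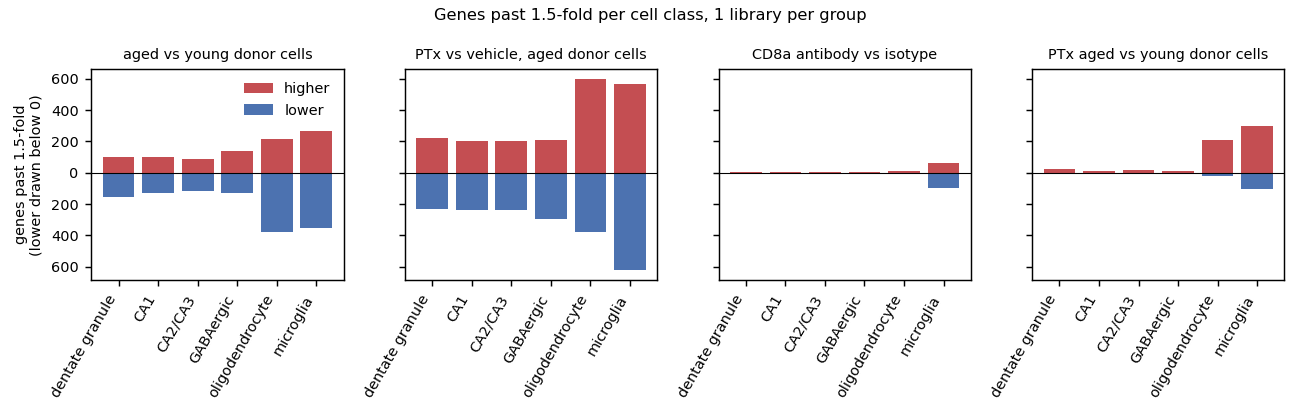
Genes past 1.5-fold in each class, higher or lower, per comparison. The sums over the 6 classes were 2175 for aged against young donor cells, 4009 for PTx against vehicle and 210 for CD8a antibody against isotype.

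In dentate granule neurons, Dalrd3 (ENSMUSG00000019039, 9:108569886–108572774, +), which encodes a partner of a tRNA methyltransferase, was at 72.3 CPM after aged and 31.3 after young cells (ratio 2.31, 2.08–2.56). C1ql3 (ENSMUSG00000049630, 2:13003457–13011806, −), a secreted C1q-like protein that binds adhesion receptors at synapses, was at 300.4 and 154 CPM (ratio 1.95, 1.86–2.04). The receptor gene Gpr171 was at 24.0 and 52.4 CPM, and Plxna4os2, antisense to the semaphorin receptor gene Plxna4, at 38.9 and 81.1 CPM. The dentate nuclei of these 2 libraries fell into different clusters: cluster 11 held 81.9% of those after aged and 2.49% of those after young cells. Median UMIs were 7014 in cluster 11 and 3991 in cluster 10. Those of the dentate nuclei were 8228 after aged and 4827 after young cells, so this split cannot be told apart from depth.

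In CA1, the mitochondrial ribosomal gene Mrpl41 (ENSMUSG00000036850) was at 51.4 CPM after aged and 22.7 CPM after young cells (ratio 2.26) and Rprml, a relative of the cell cycle gene reprimo, at 53.7 and 24.9 CPM. Lower genes were Polq (ENSMUSG00000034206, 16:37011786–37095417, +), which encodes DNA polymerase theta, at 43.0 and 99.6 CPM, and Pebp4, for a phosphatidylethanolamine-binding protein, at 27.4 and 59.7 CPM. In CA2/CA3 neurons, Ndufaf4 (ENSMUSG00000028261, 4:24898083–24905001, +), an assembly factor of respiratory complex I, was at 82.2 and 37.2 CPM (ratio 2.21, 1.95–2.52) and Dalrd3 at 81.6 and 38.4 CPM, while Polq was at 82.9 and 182 CPM and Plxna4os2 at 24.1 and 53.4 CPM.

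In GABAergic interneurons, the peptide gene Sst (ENSMUSG00000004366, 16:23889573–23890958, −) was at 102 CPM after aged and 35.8 CPM after young cells (ratio 2.85, 2.50–3.25), and Npy (ENSMUSG00000029819, 6:49822710–49829507, +) at 53.8 and 18.5 CPM (ratio 2.91, 2.43–3.50). As background in classes that do not make these peptides, Sst was counted at 50.6 and 44.7 CPM and Npy at 26.9 and 18.5 CPM in oligodendrocytes, but in dentate granule neurons Sst was at 12.6 and 12.4 CPM and Npy at 6.66 and 5.41 CPM, and in CA1 Sst was at 6.99 and 8.77 CPM and Npy at 4.40 and 3.18 CPM. Grip1os1, antisense to the synaptic scaffold gene Grip1, was at 193 and 417 CPM, and Alas2, which encodes the erythroid enzyme that starts haem synthesis, at 52.3 and 105 CPM.

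Oligodendrocytes had Sgk1 (ENSMUSG00000019970, 10:21882184–21999903, +), a kinase induced by glucocorticoids, at 249 CPM after aged and 70.0 CPM after young cells (ratio 3.56, 3.13–4.06). Ptgds (ENSMUSG00000015090, 2:25466709–25470046, −), the prostaglandin D2 synthase, was at 1148 and 364 CPM (ratio 3.16, 2.98–3.34). The protease gene Prss48 was at 37.9 and 91.2 CPM and the homeobox gene Zfhx2 at 301 and 615 CPM. Microglia had Cst3 (ENSMUSG00000027447, 2:148871722–148875692, −), which encodes the protease inhibitor cystatin C, at 692 and 272 CPM (ratio 2.55, 2.18–2.98), and Mir142hg, the host gene of the immune microRNA miR-142, at 326.5 and 127 CPM (ratio 2.57, 2.05–3.25). Gngt2, a G protein gamma subunit, was at 111 and 251 CPM and Insyn2b at 572 and 999.6 CPM.

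Genes of protein synthesis and respiration had higher medians after aged cells in each of the 6 classes, with the gene length trend left in. The random lists were matched on expression and not on gene length. The median log2 ratio of cytosolic ribosomal protein genes was 0.95 in dentate granule neurons (22 members), 0.97 in CA1 (16), 0.87 in CA2/CA3 (13), 1.02 in GABAergic interneurons (19), 0.73 in oligodendrocytes (27) and 0.79 in microglia (27). Among them, Rpl6 was at 104 and 51.0 CPM in dentate granule neurons, and Rpl41 at 122 and 42.7 CPM in microglia. Nuclear-encoded oxidative phosphorylation genes had medians of 0.60, 0.72, 0.61, 0.75, 0.56 and 0.39 in the same order of classes, with Cox4i1 at 64.5 and 31.8 CPM in dentate granule neurons and Cox7b at 70.3 and 26.7 CPM in interneurons. Heat shock and chaperone genes had medians of 0.28, 0.29, 0.30 and 0.32 in the 4 neuronal classes and 0.20 in oligodendrocytes, where Cryab was at 203 and 103 CPM. With the gene length trend removed, the ribosomal medians in dentate granule, CA1 and CA2/CA3 neurons were 0.37, 0.48 and 0.51, while those of the heat shock list were 0.01, 0.03, 0.09 and 0.06 in the neuronal classes and −0.06 in oligodendrocytes. Non-coding RNAs also differed between the transfer libraries: over all kept nuclei Malat1, which stays in the nucleus, was at 57213, 79997 and 51292 CPM after young, aged and PTx-treated cells, and AY036118 at 2159, 1239 and 4180 CPM, chosen for naming after their values were seen.

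Other lists of neurons lay closer to 0. Axon guidance and neuronal adhesion genes had a median of −0.13 in dentate granule neurons and −0.16 in CA1, each with 19 of 22 members lower. The 4 medians of voltage-gated ion channels were −0.10, −0.11, −0.12 and −0.12, those of glutamate receptors −0.09, −0.07, −0.07 and −0.07, those of presynaptic release 0.02, 0.01, 0.00 and −0.02, and those of plasticity signalling −0.07, −0.08, −0.12 and −0.07, none of them among the outermost 2.5% of random lists on either side. Clock genes were higher in CA2/CA3, with a median of 0.29 over 9 members and Per3 at 51.6 and 33.9 CPM. Long nuclear RNAs had medians of 0.06 in CA1 and 0.01 in CA2/CA3 but −0.73 in oligodendrocytes and −0.62 in microglia. With the length trend removed, the values of CA1 and CA2/CA3 were −0.075 and −0.096. The CA2/CA3 value was −0.11 with nuclei thinned to 1000 UMIs. Meg3 was at 830 and 1532 CPM in oligodendrocytes, and Snhg14 at 104 and 245 CPM in microglia.

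In oligodendrocytes, all 18 myelin and mature oligodendrocyte genes were higher after aged cells (median log2 ratio 0.59), among them Apod at 614 and 272 CPM, Mal at 504 and 257 CPM and Cnp at 309 and 174 CPM. Ageing and injury genes of oligodendrocytes had a median of 0.48 over 5 members, which included Sgk1 and Il33 (504 and 362 CPM). The glucocorticoid response list, with 7 of 8 members higher, was at 0.75, with Mt1 at 64.3 and 23.8 CPM and Errfi1 at 60.9 and 35.2 CPM. All 11 cholesterol synthesis genes were higher (median 0.30), such as Msmo1 at 66.4 and 40.2 CPM. Neuronal marker genes were counted in oligodendrocytes at 7901 CPM after aged and 8463 CPM after young cells, while the marker genes of the class itself were at 16850 and 13947 CPM.

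In microglia, genes of the disease-associated state were higher after aged cells, with a median log2 ratio of 0.71 over 9 members, 8 of them higher. Tyrobp, the signalling adaptor of Trem2, was at 108 and 47.9 CPM, the lysosomal proteases Ctsd and Ctsb at 221 and 104 and at 160 and 81.6 CPM, and Trem2 at 155 and 88.1 CPM. The 14 homeostatic genes were higher as well (median 0.35), with Tmem119 at 120 and 60.9 CPM and Gpr34 at 669 and 454 CPM. MHC class I genes were at 0.66, all 6 higher, with B2m at 74.9 and 46.6 CPM, and glucocorticoid response genes at 0.57, with Fkbp5 at 244 and 149 CPM. The interferon response list was at 0.37 in microglia and 0.21 in oligodendrocytes, not among the outermost 2.5%. Neuronal markers in microglia were at 2400 and 2632 CPM, and the markers of microglia at 7095 and 5852 CPM.

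**Figure D2:**
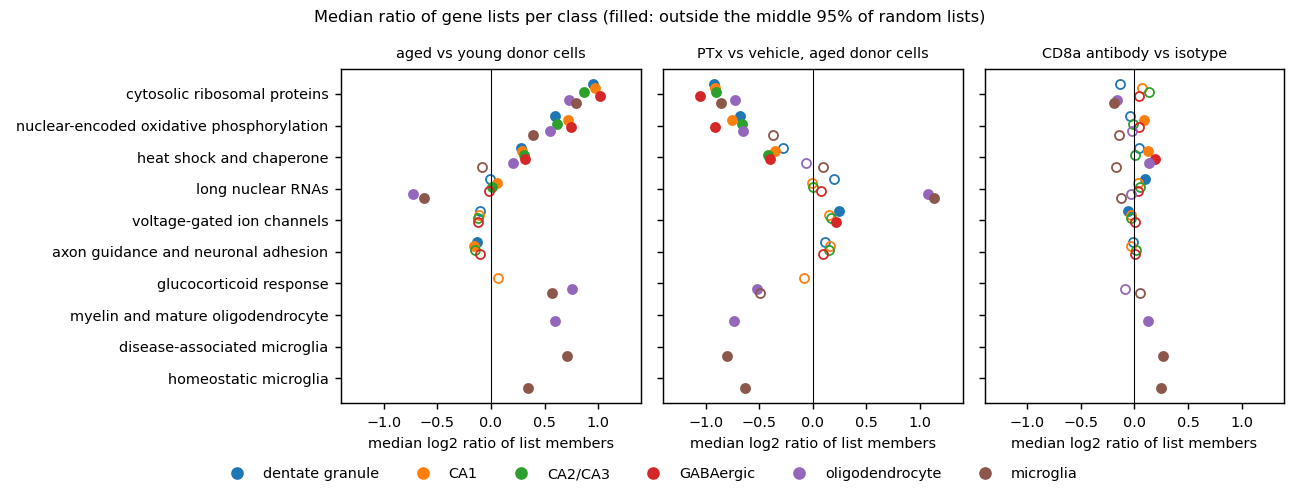
Median log2 ratio of gene lists in each class. In microglia, the disease-associated list was at 0.71, −0.80 and 0.27 for aged against young donor cells, PTx against vehicle and CD8a antibody against isotype.

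The second comparison set recipients of PTx-treated aged CD8+ T cells against recipients of vehicle-treated aged cells. PTx inactivates Gi/o proteins, through which chemokine receptors guide T cells into lymph nodes. Genes that follow the migration of aged cells would be moved back towards their level after young cells. PTx also inhibits other Gi/o signals of the T cells.

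Past 1.5-fold were 4009 results, 1998 higher and 2011 lower with PTx. The counts were 221 higher and 231 lower in dentate granule neurons, 200 and 239 in CA1, 205 and 238 in CA2/CA3, 207 and 298 in GABAergic interneurons, 600 and 380 in oligodendrocytes and 565 and 625 in microglia. In microglia the median over all genes was itself −0.14, and with ratios centred on the median gene of each class the sum was 3830, 2178 higher and 1652 lower. Of the kinds of genes left out of naming were 111, 125, 119 and 117 of the higher genes in the 4 neuronal classes, in the order above. Among the lower genes they were 14, 11, 12 and 14. The correlation with gene length lay between 0.392 and 0.560, opposite to that of the first comparison. With the length trend removed, 1958 results were higher and 1029 lower. Lower in all 6 classes were 32 genes, among them Srsf7, Clk1, Clk4, Son, Hnrnpa2b1 and Rbm39, and higher in all 6 were 15, among them the adaptor gene Shb and the non-coding RNAs AY036118 and Gm26917 (genes chosen for naming after their values were seen).

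In dentate granule neurons, the coiled-coil gene Ccdc33 (ENSMUSG00000037716) was at 101 CPM with PTx and 35.4 CPM with vehicle (ratio 2.87, 2.60–3.16) and Plxna4os2 at 95.7 and 38.9 CPM. The splicing factor gene Srsf7 (ENSMUSG00000024097, 17:80200080–80207307, −) was at 86.6 and 246 CPM, 2.84-fold lower (2.66–3.03), and Gas5, a non-coding host of small nucleolar RNAs, at 28.5 and 76.2 CPM. Cluster 10 held 98.9% of the dentate nuclei with PTx and 18.1% with vehicle, whose median UMIs were 3318 and 8228. In CA1, Taco1 (ENSMUSG00000001983, 11:106066061–106073612, +), which activates translation of mitochondrial COX1, was at 63.5 and 15.3 CPM (ratio 4.16, 3.64–4.76) and Alas2 at 117 and 46.4 CPM, while Srsf7 was at 84.8 and 259 CPM and Ndufaf4 at 32.6 and 84.7 CPM. CA2/CA3 neurons had the same kind of genes: Taco1 at 67.5 and 14.4 CPM (ratio 4.67, 3.96–5.54), Alas2 at 120 and 47.7 CPM, Ndufaf4 at 27.5 and 82.2 CPM and Dalrd3 at 29.8 and 81.6 CPM.

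In GABAergic interneurons, Taco1 was at 68.7 CPM with PTx and 19.0 CPM with vehicle and Alas2 at 126 and 52.3 CPM. Sst was at 27.5 and 102 CPM, 3.71-fold lower (3.23–4.28), against 45.5 and 50.6 CPM in oligodendrocytes, 14.4 and 12.6 CPM in dentate granule neurons and 7.35 and 6.99 CPM in CA1, and Ate1, an enzyme that attaches arginine to proteins, at 20.9 and 74.7 CPM. Oligodendrocytes had Ctcflos, antisense to Ctcfl, at 56.3 and 10.3 CPM (ratio 5.48, 4.13–7.38) and the semaphorin gene Sema3c at 65.8 and 12.7 CPM. Ptgds was at 282 and 1148 CPM, 4.07-fold lower (3.85–4.30), and Apoe (ENSMUSG00000002985, 7:19696109–19699188, −), the main lipid carrier of the brain, at 68.1 and 236 CPM, 3.47-fold lower (3.09–3.90). Microglia had Shb (ENSMUSG00000044813, 4:45423278–45532470, −), an adaptor of tyrosine kinase receptors, at 737 and 193 CPM (ratio 3.82, 3.26–4.50) and the proteoglycan gene Spock2 at 103 and 35.5 CPM. C1qa (ENSMUSG00000036887, 4:136895917–136898803, −), which starts the classical complement pathway and marks synapses for removal, was at 84.4 and 326.5 CPM, 3.87-fold lower (3.01–5.03), and Cst3 at 204 and 692 CPM, 3.39-fold lower (2.88–4.00).

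The medians of the lists in this paragraph were opposite in sign to those of the first comparison in the same classes. Ion channels and plasticity signalling were not among the outermost 2.5% there. Ribosomal protein genes had medians of −0.92, −0.92, −0.91, −1.06, −0.72 and −0.86 from dentate granule neurons to microglia, and oxidative phosphorylation genes −0.68, −0.76, −0.67, −0.92 and −0.65 in neurons and oligodendrocytes; the −0.37 of microglia was not among the outermost 2.5% of random lists. Heat shock genes were at −0.35 in CA1, −0.42 in CA2/CA3 and −0.40 in GABAergic interneurons; the last was 0.04 with the length trend removed. Voltage-gated ion channels were higher with PTx, at 0.25 in dentate granule neurons (Kcnq5 at 138 and 46.1 CPM) and 0.22 in interneurons (Cacna1e at 228 and 140 CPM). Plasticity signalling genes were at 0.20 in CA2/CA3, with 14 members higher and 8 lower and Mef2c at 82.1 and 44.1 CPM.

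In oligodendrocytes with PTx, all 18 myelin genes were lower (median −0.73), with Apod at 257 and 614 CPM. Ageing and injury genes were at −0.71 and glucocorticoid response genes at −0.52, while long nuclear RNAs were at 1.08, with Meg3 at 2719 and 830 CPM. In microglia, disease-associated genes were at −0.80, with Tyrobp at 30.0 and 108 CPM, and the 14 homeostatic genes, all lower, at −0.63, with Gpr34 at 250 and 669 CPM. Protease-activated and cytokine receptors were at −0.44 and long nuclear RNAs at 1.13. Mitochondrially encoded transcripts were at −1.24 in microglia, and at 0.36 in the stricter set of nuclei. Marker genes of the class were at 4808 CPM with PTx and 7095 with vehicle in microglia, and at 12132 and 16850 CPM in oligodendrocytes. Neuronal markers were at 2916 and 2400 CPM in microglia and at 8052 and 7901 CPM in oligodendrocytes. The oligodendrocytes of the libraries lay in different clusters: cluster 0 held 49.2% of them with PTx and 73.1% with vehicle, cluster 1 27.8% and 23.6%, and cluster 2 1198 of 5208 and 86 of 2588 nuclei. After young cells, clusters 0, 1 and 2 held 70.5%, 23.5% and 5.98%.

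The ratios of the 2 transfer comparisons ran opposite to each other across genes. With the nuclei of the shared library split so that each comparison used its own part, the correlation had a median of −0.876 over the classes (−0.891 to −0.718); genes are not independent replicates. Over 100 simulations of unchanged groups, with counting error only, the typical correlation per class was −0.0021 to 0.0026 with the nuclei split. The low and high bounds of these simulations reached −0.0375 and 0.0458. With all nuclei, which the counts below use, the typical correlations were −0.458 to −0.383, with bounds that reached −0.483 and −0.354. Of results past 1.5-fold in both, 757 were higher after aged cells and lower with PTx, 1098 were lower and then higher, and none went the same way. A single library, that of the vehicle-treated aged cells, enters both comparisons, which by itself favours opposite calls.

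**Figure D3:**
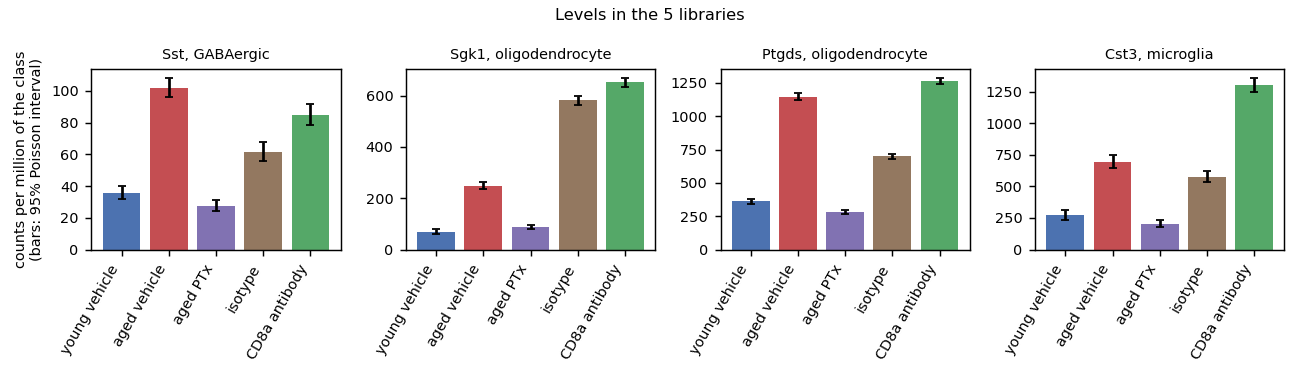
Levels of named genes in the 5 libraries with counting intervals. Ptgds in oligodendrocytes was at 364, 1148, 282, 699 and 1264 CPM and Cst3 in microglia at 272, 692, 204, 575 and 1301 CPM after young, aged and PTx-treated cells, with isotype and with CD8a antibody.

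PTx-treated aged cells against young cells, a comparison without the shared library, gave 727 results past 1.5-fold, 573 higher and 154 lower, of which 233 were in oligodendrocytes and 402 in microglia. The sum was 439 with the strict filter and 418 with the length trend removed. With nuclei thinned to 1000 UMIs, 435 were higher and 260 lower, but shallower nuclei were left out, 732 of 982 microglia with PTx and 210 of 661 after young cells. Taco1 was higher in CA1 (ratio 3.11, 2.73–3.54), CA2/CA3 (3.67, 3.06–4.42) and interneurons (2.68, 2.29–3.15), and Shb in oligodendrocytes (629 and 275 CPM) and microglia (737 and 313 CPM). Srsf7 was lower in dentate granule neurons (86.6 and 149 CPM), CA1 (84.8 and 159 CPM), oligodendrocytes (127 and 212 CPM) and microglia (152 and 291 CPM). Lower too were Hnrnph1 in dentate granule neurons (111 and 183 CPM), the activity-regulated kinase gene Plk2 in CA1 (82.5 and 134 CPM), the BMP antagonist gene Chrd in CA2/CA3 (51.5 and 98.1 CPM) and Zranb2 and Rsrp1 in interneurons (325 and 506, 278 and 433 CPM). Ion channels were at 0.12 in dentate granule neurons, 0.08 in CA1 and 0.11 in interneurons, with Kcnq5 at 138 and 76.5 CPM in the first. Myelin genes were at −0.19 and the interferon response list in microglia at 0.45, with 11 of 12 members higher and Rnf213 at 95.5 and 63.4 CPM. Ribosomal protein genes lay between −0.07 and 0.03 in the 5 classes with enough members. The correlation with gene length was 0.196 to 0.382.

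The depletion comparison set aged mice given the CD8a antibody against aged mice given the isotype control. The antibody removes CD8+ T cells from the blood of mice that have lived with them to old age. The aged hippocampus holds more reactive microglia and damaged myelin, and the comparison shows which of these states differ after depletion.

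Past 1.5-fold lay 210 results, 89 higher and 121 lower with the antibody (118 and 107 with ratios centred on the median gene). The sum was 350 with thinned nuclei and 417 with free RNA subtracted. Of them, 7 were in dentate granule neurons, 7 in CA1, 8 in CA2/CA3, 7 in GABAergic interneurons, 21 in oligodendrocytes and 160 in microglia (64 higher, 96 lower). No gene was higher in 4 or more classes, and 1, Ide, was lower in 4. The correlation with gene length lay between −0.212 and 0.0227. Cluster 11 held 99.3% and 99.9% of the dentate nuclei of these 2 libraries, and of oligodendrocytes cluster 2 held 51.7% with isotype and 43.6% with the antibody.

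In dentate granule neurons with the antibody, the E3 ligase gene Dtx3 was at 109 against 80.0 CPM and the splicing factor gene Srsf9 at 70.8 against 51.1 CPM. Zmym1, a zinc finger gene, was at 35.3 against 76.7 CPM, 2.17-fold lower (1.94–2.43), and Unc13c, a vesicle priming factor, at 32.4 against 54.1 CPM. In CA1, Dalrd3 was at 101 against 68.7 CPM (ratio 1.48, 1.35–1.62) and Traip, an E3 ligase of DNA repair, at 130 against 90.0 CPM, while the adhesion gene Sdk2 was at 46.3 against 67.3 CPM and the brain glycogen phosphorylase gene Pygb at 46.2 against 66.0 CPM. In CA2/CA3, Dalrd3 was at 98.8 against 59.0 CPM (ratio 1.68, 1.47–1.91) and the metalloprotease gene Adam15 at 54.1 against 32.5 CPM. Ide (ENSMUSG00000056999, 19:37268743–37337852, −), an enzyme that degrades insulin and amyloid β, was at 43.4 against 65.9 CPM there and at 45.7 against 77.8 CPM in interneurons, 1.70-fold lower (1.48–1.96). Tspan18 was at 44.9 against 67.6 CPM in CA2/CA3. Interneurons had the sorting nexin gene Snx32 at 128 against 84.6 CPM, the Polycomb gene Ring1 at 58.0 against 37.0 CPM and Ate1 at 35.7 against 63.9 CPM.

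Oligodendrocytes had Ptgds at 1264 CPM with the antibody and 699 CPM with isotype (ratio 1.81, 1.75–1.87), and the channel gene Hcn2 at 68.6 and 39.2 CPM. Rhoj, a small GTPase, was at 56.6 and 108 CPM. Ttr (ENSMUSG00000061808, 18:20665280–20674321, +), the thyroid hormone carrier made by the choroid plexus, was at 12.2 and 77.8 CPM, 6.37-fold lower (5.16–7.92), with 12.2 and 73.0 CPM in microglia and 2.91 and 19.4 CPM in dentate granule neurons. Choroid plexus nuclei numbered 2 with isotype and 0 with the antibody. In droplets without a called nucleus Ttr was at 22.4 CPM with the antibody and 212 CPM with isotype. Microglia had Cst3 at 1301 and 575 CPM (ratio 2.26, 2.08–2.46) and Xbp1, a transcription factor of the unfolded protein response, at 54.1 and 21.5 CPM (ratio 2.52, 1.62–4.01). The myelin gene Mal was at 39.9 and 90.6 CPM in microglia.

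In microglia, disease-associated genes had a median of 0.27 with the antibody, with 7 members higher and 3 lower, Ctsd at 520 and 343 CPM and Trem2 at 196 and 141 CPM. All 14 homeostatic genes were higher (median 0.25), with Tmem119 at 213 and 156 CPM, and so were cytokine receptor genes (0.20), with Ifngr1 at 161 and 119 CPM. C1qa was at 375 and 235 CPM. The marker genes of microglia were at 7897 and 6835 CPM and neuronal markers at 3047 and 3110 CPM. Free RNA was estimated at 20.4% of the UMIs of microglia with the antibody and 25.0% with isotype, and at 25.7% and 31.2% in oligodendrocytes. Part of the higher glial medians cannot be told apart from this difference. Of 70 list medians with free RNA subtracted, 63 stayed in or out of the outermost 2.5%, 3 left it, 2 entered it, 1 moved and 1 reversed. For those that stayed out of it, a change of sign was not counted. MHC class I genes (0.23) and the interferon response list (0.14) were not among the outermost 2.5% of random lists.

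In oligodendrocytes, myelin genes had a median of 0.13, 14 higher and 4 lower, with Apod at 901 and 661 CPM and Mag at 967 and 807 CPM. Heat shock genes were at 0.14 in oligodendrocytes (Cryab at 125 and 78.3 CPM), 0.13 in CA1 and 0.19 in interneurons (Hspa8 at 81.3 and 55.2 CPM). Ribosomal protein genes were at −0.16 in oligodendrocytes, or 0.05 with free RNA subtracted, and at −0.19 in microglia. Mitochondrially encoded transcripts were at −0.90 and −1.34, with mt-Co3 at 61.2 and 177 CPM in microglia. In neurons, immediate early genes were at 0.17 in CA1 over 5 members, with Homer1 at 296 and 255 CPM, oxidative phosphorylation genes at 0.09 in CA1 (−0.01 with thinned nuclei), ion channels at −0.06 and long nuclear RNAs at 0.10 in dentate granule neurons. The 4 neuronal medians of glutamate receptors were 0.01, 0.01, −0.04 and 0.02 and those of presynaptic release −0.01, −0.04, −0.02 and −0.02.

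Between the comparison of aged with young donor cells and the depletion comparison, which share no library, the correlation across genes was 0.0999 as a median over the classes (−0.0235 to 0.246), and 0.223 for the genes past 1.5-fold in the transfer, where interneurons had 0.0920 in place of −0.0235. Higher in both were 21 results, where independent calls would give 2.88, and 7 were lower in both (3.39). They included Cst3, C1qa, C1qb, C1qc, Ctsd and Ctsz in microglia, Ptgds and Cryab in oligodendrocytes, Dalrd3 in CA2/CA3 and Ring1 in CA1 and interneurons, chosen for naming after their values were seen. Higher after aged cells and lower with the antibody were 6 (2.44 for independent calls), among them Ate1 in interneurons, and 1 was lower and then higher (3.99). Both comparisons favoured shorter genes, with median Spearman correlations with gene length of −0.433 and −0.166 over the classes. The overlaps are not given with the length trend removed, so they cannot be told apart from this shared trend. Independent calls also take genes and classes as unrelated.

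T cells themselves were not seen as a class, and no cluster was named T cell. Cd8a (6:71373427–71379173, +) was counted 24, 11 and 19 times in the transfer libraries and 3 and 6 times with isotype and CD8a antibody. Trac, the constant region of the T cell receptor, was counted 31, 20, 43, 9 and 4 times, Cd3e 1, 1, 1, 0 and 0 times, and Gzmb and Nkg7 were not counted. Nuclei with 2 or more of the genes Cd3d, Cd3e, Cd3g, Cd8a, Cd8b1, Trac and Trbc2 numbered 0, 0, 1, 0 and 1, and nuclei with 1 or more of them 84, 65, 124, 36 and 38. The T cell and cytotoxic genes without Tox, which neurons express, summed to 698, 1053, 519, 448 and 491 UMIs per 10000 nuclei, or 12.4, 11.3, 12.7, 9.50 and 8.63 CPM of all UMIs. Most of these were Gzmk, with 909 of 1215 UMIs after aged cells. Ccl5, a chemokine of effector T cells, was counted 296, 221, 383, 62 and 74 times. These counts are not particular to T cells. After young cells 58, 44, 25 and 45 lay in dentate granule, CA1, CA2/CA3 and GABAergic neurons, against 6 in oligodendrocytes and 2 in microglia. Gzmk (ENSMUSG00000042385, 13:113171608–113225908, −), the granzyme of aged CD8+ T cells, was counted 665, 909, 757, 609 and 607 times, or 7.63, 8.44, 7.34, 7.97 and 7.00 CPM of all UMIs. Among the 6 compared classes it was highest in CA1 neurons, at 14.3, 15.6, 14.9, 16.7 and 14.2 CPM, and its annotated span overlaps that of Esm1 (13:113209659–113218098, +) on the other strand.

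**Figure D4:**
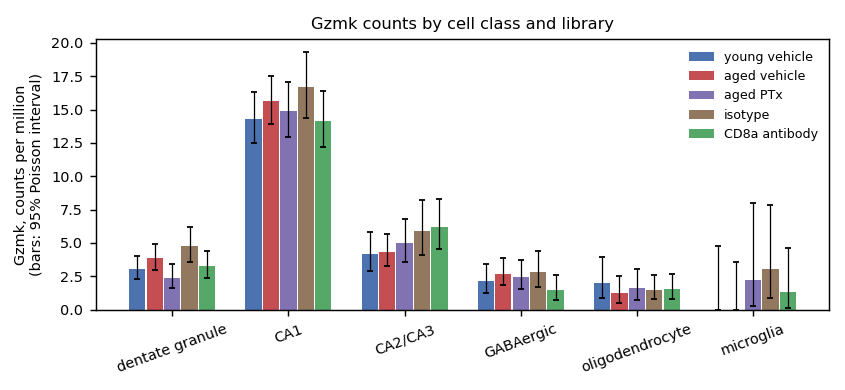
Gzmk levels (CPM) by class and library. In CA1 neurons they were 14.3, 15.6, 14.9, 16.7 and 14.2 after young, aged and PTx-treated cells, with isotype and with CD8a antibody.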

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

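Of the tests below, only that of neuronal RNA in glia was chosen before its result was seen; all others were chosen after. Genes of the T cell list were also counted in droplets without a called nucleus, which no comparison uses: the T cell and cytotoxic genes without Tox had 259 UMIs there with isotype and 243 with CD8a antibody, of which 210 and 190 were Gzmk. Per 34801522 and 33804928 uncalled UMIs this made 6.03 and 5.62 CPM of Gzmk, against 7.97 and 7.00 CPM in called nuclei. Cd8a was not counted in these droplets in either library, and counts of Gzmk alone do not show RNA of T cells.

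The ratios after transfer of aged cells were alike in unlike classes, and ran the opposite way with PTx. With the length trend subtracted, 228 of the 912 higher results stayed past the rule, so that gene length bias may account for most of these, and for part of the lower results of microglia and oligodendrocytes, of which 372 of 729 stayed; for the lower results of neurons it is argued against, since 501 of 534 stayed. The median correlation of 0.655 between pairs of classes may come from the preparation of the vehicle-treated aged library or from a systemic effect in the mice, but likeness of the classes is not particular to that library: the median was 0.540 for PTx against young cells, without it, and 0.314 with CD8a antibody. An effect of aged CD8+ T cells that PTx removes cannot be told apart from a property of that 1 library, because the correlation of −0.876 with PTx against vehicle has this sign in either case. Of the genes past the rule for PTx against vehicle, 87.7% to 93.9% per class had a young level between those with vehicle and PTx. These genes were picked for a gap of 1.5-fold or more between vehicle and PTx, which by itself favours a young level between them. The share thus does not show that PTx went past the young level. The order also follows median UMIs per nucleus (aged 7809, young 4916, PTx 3603). Properties of the young and PTx libraries are not excluded either. Second libraries of each transfer group would be needed.

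In microglia and oligodendrocytes, glial genes were higher after aged cells and lower with PTx. Neuronal RNA in the droplets would shift glia-restricted genes by 1 factor, but 13.4% of them (86 of 641) had an interval wholly below the young level while 269 lay above. This argues against it as the whole cause. With PTx against vehicle, 249 of 414 such genes in microglia and 148 of 227 in oligodendrocytes lay wholly below, and 31 and 33 above. The length trend acts on these genes too, so neuronal RNA as a part of the cause is not excluded. Gene length bias is argued against for the disease-associated list, still at 0.48 with the length trend subtracted, but may account for most of the genes higher in these classes, of which 172 of 484 stayed past the rule. An effect of aged CD8+ T cells on glia cannot be told apart from the library difference: the list was at 0.27 with CD8a antibody, where a loss of such an effect would have given a value below 0, but these were other mice of another age under another intervention, so that this value does not exclude it in the transfer.

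Gzmk was counted in each library, and among the 6 compared classes it was highest in CA1 neurons. Free RNA of T cells is argued against for the CA1 counts, because Gzmk was 4.38-fold higher (3.81–5.05) in CA1 than in dentate granule nuclei (15.1 against 3.45 CPM). Nuclei of T cells among the CA1 nuclei could not be judged as a source. Of 7995 CA1 nuclei 875 held Gzmk, and 4 of these, 0.457% (0.125–1.17%), held a T cell receptor or Cd3 gene. The rate at which T cell nuclei show these genes was not measured, so T cell nuclei are not excluded. Among all nuclei of each library, and with the CD8 genes added, 84 of 15527, 65 of 11533, 124 of 25161, 36 of 16194 and 38 of 15237 had 1 or more. An RNA of CA1 neurons from the Gzmk locus is a candidate explanation, as the CA1 level varied 1.18-fold over the 5 libraries, with or without CD8a antibody.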

How the results depend on the processing

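Removal of the gene length trend and subtraction of the other classes were chosen after the data were seen; the other settings were planned. Of 2818 list medians under alternatives, 2596 stayed in or out of the outermost 2.5%, 121 left it, 85 entered it, 7 moved and 9 reversed. A median outside the outermost 2.5% in both settings counted as kept even if its sign changed. Reversals were counted only among medians in the outermost 2.5% in the main setting. Of 768 log2 ratios of named genes none reversed and 101 moved, among them 38 of 96 with the length trend removed and 33 of 96 with thinned nuclei. Sums of genes past the rule stayed within 1.5 times for each comparison without doublet removal, at Leiden resolution 2, centred and with equal weight, and with the aggregate matrix for the transfer comparisons. Aged against young, PTx against vehicle, CD8a antibody against isotype and PTx against young, without a CPM minimum and with 20 UMIs, gave 21479, 29249, 9590 and 10788, as more genes were tested, and the 2-fold rule gave 402, 1320, 25 and 64, as it is stricter. Less the other classes, the first 3 gave 675, 1571 and 128. CD8a antibody gave 350 with thinned nuclei and 417 with free RNA subtracted, and PTx against young 439 with the strict filter and 418 with the length trend removed. Reversed medians of aged against young were long nuclear RNAs in CA2/CA3 (−0.11 thinned, −0.096 length removed, −0.0101 with pseudocount 1) and CA1 (−0.075 length removed) and heat shock in oligodendrocytes (−0.062 length removed). Reversed too were, with PTx against vehicle, mitochondrial transcripts in microglia (0.36, strict filter) and heat shock in GABAergic interneurons (0.042, length removed), and with CD8a antibody oxidative phosphorylation in CA1 (−0.0052 thinned) and ribosomal proteins in oligodendrocytes (0.049, free RNA subtracted). The correlation of aged against young with CD8a antibody in interneurons was 0.0920 for genes past 1.5-fold and 0.00801 thinned, and its median over classes 0.223 for genes past 1.5-fold. The split-nuclei correlation with PTx was −0.615 thinned. In kept nuclei T cell UMIs per 10000 were 473 with PTx, 551 with isotype and 556 with CD8a antibody. Of 220 class percentages under alternatives, 93 left the counting interval of the main value. These were 48 of 75 with the strict filter, 23 of 70 at Leiden resolution 2 and 22 of 75 without doublet removal. Beyond the reasons named, the cause was not tested. Free RNA could be subtracted only in the depletion comparison. No paired analysis was possible because each group is 1 library. Depth limits microglia most: thinning kept 250 of 982 nuclei with PTx.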

Other observations

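All values below were looked at after the data were seen, and no test was run on them. Sgk1 in oligodendrocytes was at 70.0, 249 and 85.9 CPM after young, aged and PTx-treated cells and at 581 and 652 CPM in the aged mice with isotype and CD8a antibody, and Apoe at 111, 236, 68.1, 248 and 368 CPM in the same order. Insyn2b in microglia was at 999.6, 572, 979.6, 146 and 190 CPM, Polq in CA2/CA3 neurons at 182, 82.9, 189.8, 29.4 and 29.1 CPM, and Shb in oligodendrocytes at 275, 156, 629, 36.6 and 33.2 CPM. Dalrd3 in CA1 neurons was at 43.5, 83.6, 33.2, 68.7 and 101 CPM.

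Oligodendrocyte precursors made up 2.04%, 1.45%, 1.61%, 1.79% and 2.36% of kept nuclei, with 287, 155, 352, 213 and 277 nuclei. Cajal-Retzius neurons, the reelin-making cells that guide hippocampal development and of which some persist in the adult, numbered 83, 61, 157, 44 and 78, and hilar mossy cells 78, 64, 118, 51 and 45. Subicular and cortical excitatory neurons numbered 636, 483, 1292, 458 and 449, and choroid plexus cells 14, 7, 0, 2 and 0. Thalamic or habenular markers came closest in unnamed clusters that held 0.688%, 0.672%, 2.71%, 0.815% and 1.16% of nuclei.

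Ttr, a marker of choroid plexus, was at 108, 128, 45.4, 77.8 and 12.2 CPM in oligodendrocytes.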
